A study of Homo sapiens with 12 samples.

How the data were processed

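RNA enriched for mRNA was sequenced in 12 libraries of human aortic endothelial cells (HAECs), primary cells that line the aorta, used between passages 2 and 5. The cells had been transfected for 3 days with a control siRNA (siCtrl) or an siRNA against FOXO1 (siFOXO1) and then kept static or exposed for 24 h to oscillatory shear stress (OSS) of 0.5 ± 4 dynes/cm2. There were 3 libraries in each of the 4 groups. The labels do not say whether the replicates of a group came from separate donors, separate cultures or a single culture. The p-values therefore measure only the spread between these libraries, which may be technical.

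The authors' processing notes name bcl2fastq, HISAT2 2.1.0, HTSeq 0.11.1 and DESeq2 1.24, and both the hg19 and GRCh38 builds without saying which step used which. The table deposited by the authors is called raw counts, but its values are CPM (counts relative to the library total), since each column sums to 1000000 once an offset of 0.0001 added to every value is taken off. Without the offset, 100.0% of the low values of every library were whole multiples of what 1 read was worth (within a tolerance of 0.05 reads). This step size gave depths of 11.8 to 20.6 assigned reads per library, in units of 1000000, and 3 reads were worth 0.146 to 0.254 CPM. The CPM scaling and the offset are not described in the notes. The table was analysed in its deposited unit, CPM. Whole reads can be worked back from it, but no count model was fitted to them, and the planned count-based test was replaced by limma on the log scale.

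The table lists 24878 genes by Ensembl identifier, 5204 of them without a gene symbol, and 24249 identifiers (97.5%) were found in GENCODE release 29, which supplied the GRCh38 coordinates. Genes with at least 0.5 CPM in at least 3 libraries were tested, which left 14503. The deposited CPM were rescaled by trimmed-mean-of-M factors (TMM, trimming 30% of log ratios and 5% of mean levels), and all levels given are TMM-scaled CPM, as mean ± SD over the 3 libraries of a group. Log2 values were taken after adding 0.5 CPM, so fold changes of weakly expressed genes are understated. Fold changes are given as log2 ± standard error (SE) of the fit.

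The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend (limma-trend). A single fit of the 12 libraries with 1 coefficient per group gave 5 contrasts: OSS against static in siCtrl cells, siFOXO1 against siCtrl under OSS, siFOXO1 against siCtrl in static cells, OSS against static in siFOXO1 cells, and the interaction, which tests whether the OSS response differs with the siRNA. Adjusted p-values follow Benjamini and Hochberg over the 14503 genes of a contrast, and genes under 0.05 were called. The spread was shared by the 4 groups although the median SD per gene (log2) was 0.114 and 0.138 in the static siCtrl and siFOXO1 groups and 0.299 and 0.330 in the corresponding OSS groups. Each contrast was therefore also fitted on its own groups.

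A total of 31 gene lists, covering endothelial and shear-responsive programmes, metabolism, growth, stress responses, markers of other cell types and the mitochondrially encoded genes as a sign of RNA quality, were tested with camera (limma, inter-gene correlation preset to 0.01, with the trend). Their p-values were adjusted over the lists of a contrast. The lists were also tested with camera using a correlation estimated from the residuals and with fry, directional and mixed. Beside the number of members called over all genes stands the number called when adjusted over the list alone. The 0.5 CPM filter and the 0.5 CPM added before taking logs were not in the plan made before the data were examined. That plan fixed the contrasts, the lists, the thresholds for calling genes, most alternatives and the rule for naming genes. By that rule the text names FOXO1, FOXO3 and FOXO4, then for each contrast the 5 genes with the largest increase and the 5 with the largest decrease among called genes of at least 2 CPM on average with no overlap between replicates, and then up to 4 called members of each described list with the smallest p, or 2 members with their values where none was called. A gene named in a contrast may be given in another.

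The replicate numbers were checked as pairs by correlating, over genes, the deviations of equally numbered libraries from their group means. For siFOXO1 against siCtrl under OSS these were 0.572, 0.329 and 0.299, all above the threshold of 0.1, so blocked values stand beside that contrast. In the other contrasts at least 1 pair stayed below 0.1. The deviations within a group cancel out, so a likeness of the libraries numbered 1 alone would raise the other correlations too. Whether the OSS libraries numbered 2 and 3 are paired is therefore not shown. The relation between contrasts that share libraries was set beside 100 simulated sets of unchanged groups, drawn unpaired and with the shared spread of each gene. The alternatives were median-of-ratios and upper-quartile factors, the deposited CPM without rescaling, pseudocounts of 0.1 and 2 CPM, no filter on low values, a replicate block, fits of the compared groups only, corrections for GC content and transcript length, and leaving out each library. On data simulated from these libraries, limma called 65%, 67% and 71% of genes changed 2-fold in the first 3 contrasts and 38% in the interaction. The figures for 4-fold changes were 100% and 91%. This simulation gave all groups the shared spread, left out pairing and changed only genes of at least 2 CPM. It therefore cannot show how the wider spread of the OSS groups affects what is called. The lists shifted by 0.7 log2 in the simulation were called by camera in 100% of runs, and unshifted lists in 4%. These lists were random genes called at an unadjusted camera p under 0.05. They cannot show whether the preset correlation suits lists of genes that vary together. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9. Some single-gene results are not reported here, while counts over genes and lists are complete.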

Results

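Expression of 14503 genes was measured in 12 RNA sequencing libraries of HAECs, 3 for each combination of siRNA and flow. The series names FOXO1, a forkhead transcription factor held in the cytoplasm by insulin and AKT signalling, and asks how it takes part in the hemodynamic, inflammatory and metabolic state of endothelium in atherosclerosis. OSS models the disturbed flow of arterial regions prone to plaque. No library came from cells under steady flow, so OSS against static cannot tell a response to oscillation from a response to flow itself. Mean depth, in units of 1000000 reads, was 17.1 (14.7 to 20.6) in the static siCtrl group and 14.8 (12.8 to 16.7) in the siCtrl OSS group. It was 17.2 (14.2 to 19.4) in the static siFOXO1 group and 15.0 (11.8 to 17.2) in the siFOXO1 OSS group. The first principal component held 57.6% of the variance and set all 6 OSS libraries apart from all 6 static libraries. The second held 14.8%, and along it the OSS libraries numbered 1 of both siRNA arms lay apart from the other OSS libraries of their own group. It also set the static siCtrl libraries (9.97 to 14.0) apart from the static siFOXO1 libraries (-11.6 to -6.85). Under OSS each siFOXO1 library lay below the siCtrl library of the same number. Mitochondrially encoded genes took 6.80% ± 0.497 of the reads in static siCtrl cells, 4.15% ± 0.265 under OSS, 5.55% ± 1.53 in static siFOXO1 cells and 4.04% ± 0.585 in siFOXO1 cells under OSS (SD, n = 3 each).

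FOXO1 (ENSG00000150907, protein coding, GRCh38 chromosome 13, 40469953 to 40666597, minus strand) stood at 170.3 ± 16.9 CPM in static siCtrl cells and 186 ± 30.1 CPM under OSS. It stood at 72.8 ± 4.29 CPM in static siFOXO1 cells and at 57.7 ± 11.7 CPM under OSS (SD, n = 3). The siRNA therefore left FOXO1 57.2% lower in static cells (log2 fold change -1.22 ± 0.17, limma adjusted p = 0.00379) and 68.9% lower under OSS (-1.69 ± 0.17, limma adjusted p = 0.000245). OSS itself gave FOXO1 log2 fold changes of 0.12 ± 0.17 in siCtrl cells (adjusted p = 0.627) and -0.35 ± 0.17 in siFOXO1 cells (adjusted p = 0.115). Among its relatives, FOXO3 passed the test in none of the 5 contrasts, with 42.6 ± 1.25 CPM in static siCtrl cells and 57.7 ± 9.77 CPM under OSS. FOXO4 did not pass with the siRNA in either condition. It fell under OSS from 8.45 ± 0.792 to 4.75 ± 1.81 CPM in siCtrl cells (limma adjusted p = 0.0401) and from 8.73 ± 1.33 to 4.44 ± 1.78 CPM in siFOXO1 cells (0.0188). These FOXO4 calls were lost when single libraries were left out, in 7 of the 12 cases in siCtrl cells (adjusted p up to 0.161) and in siFOXO1 cells without static replicate 1 or 3 or OSS replicate 2 or 3 (up to 0.0721).

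**Figure D1:**
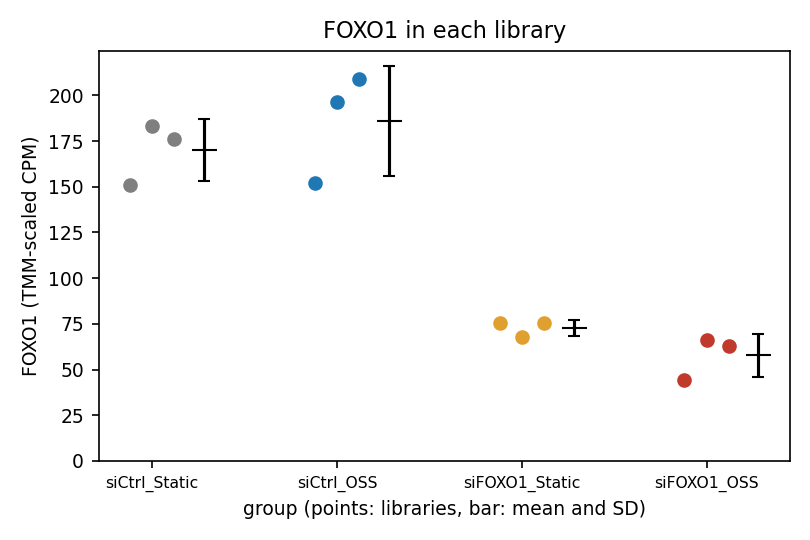
FOXO1 level in TMM-scaled CPM (vertical axis) in the 4 groups (horizontal axis), with a point for each library and a bar for the mean and SD of 3 libraries. The siFOXO1 libraries average 72.8 CPM in static cells and 57.7 CPM under OSS, against 170.3 and 186 CPM in siCtrl cells.

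The first comparison asks how control-transfected HAECs respond to OSS. The largest increases included single genes of coagulation, prostaglandin synthesis and leukocyte adhesion. F3, which encodes tissue factor, rose from 0.774 ± 0.555 to 106 ± 21.2 CPM (log2 fold change 6.46 ± 0.44). PTGS2, the inducible cyclooxygenase, rose from 44.1 ± 9.64 to 3079 ± 1225 CPM (6.06 ± 0.31), and SELE, the adhesion molecule E-selectin, from 4.07 ± 1.30 to 149 ± 99.7 CPM (4.86 ± 0.46). CYP1B1, a target of the aryl hydrocarbon receptor, rose from 2.00 ± 0.127 to 190.1 ± 110.4 CPM (6.08 ± 0.33), and HMOX1, which encodes haem oxygenase, from 14.8 ± 1.72 to 488 ± 197 CPM (4.90 ± 0.30). The largest decreases were those of the receptor tyrosine kinase KIT, from 98.9 ± 8.45 to 0.624 ± 0.407 CPM (-6.52 ± 0.26), and of the FOXO-responsive gene DEPP1, from 301 ± 23.8 to 13.3 ± 9.88 CPM (-4.96 ± 0.68). FLRT2 fell from 179.7 ± 30.9 to 7.98 ± 3.42 CPM (-4.49 ± 0.33), next to C2CD4A (-4.34 ± 0.39) and N4BP3 (-4.25 ± 0.29). Their limma adjusted p-values ran from 1.11e-08 for KIT to 0.00019 for DEPP1. In all, limma called 2476 genes higher and 2320 lower under OSS, and without siCtrl OSS replicate 3 the number lower was 1543.

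Of 23 measured genes of the inflammatory and leukocyte-adhesion list, 8 rose, 3 fell and 12 did not pass under OSS (9 and 3 adjusted over the list alone), with a median log2 fold change of 0.81. PTGS2, F3 and SELE were joined by the neutrophil chemokine CXCL8, which rose from 32.4 ± 1.85 to 493 ± 485 CPM (3.45 ± 0.51). Camera called the list (adjusted p = 0.00838), with adjusted p = 0.662 with an estimated correlation. The camera call was lost without siCtrl OSS replicate 1 (adjusted p = 0.0914). Against the static siCtrl mean, the list's median was 1.37, 0.73 and 0.05 in siCtrl OSS replicates 1, 2 and 3. Among 15 genes of the laminar-flow programme of KLF2 and KLF4, 7 rose, 3 fell and 5 did not pass (8 and 3 adjusted over the list alone). Camera did not call this list (adjusted p = 0.103; adjusted p = 0.579 with an estimated correlation). KLF4, a transcription factor known for its induction by steady flow, rose from 0.833 ± 0.330 to 12.9 ± 6.43 CPM (3.22 ± 0.37), and CYP1A1 from 7.76 ± 3.04 to 52.5 ± 9.68 CPM (2.73 ± 0.30). GJA4, an arterial connexin, fell from 26.4 ± 5.28 to 3.12 ± 1.38 CPM (-2.96 ± 0.29).

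Genes of the antioxidant transcription factor NRF2 rose under OSS, 8 of 14 higher and none lower (8 and 0 adjusted over the list alone), with a median of 0.72. Beside HMOX1 they included TXNRD1, from 487 ± 41.8 to 2561 ± 248 CPM (2.39 ± 0.15), and the cystine importer SLC7A11, from 285 ± 12.9 to 2210.1 ± 557 CPM (2.92 ± 0.28). The quinone reductase gene NQO1 rose from 84.2 ± 5.92 to 176 ± 10.2 CPM (1.06 ± 0.11). Camera gave adjusted p = 0.00019, and adjusted p = 0.163 with an estimated correlation. Autophagy and lysosome genes were higher as a list (8 of 18 higher, none lower, 9 and 0 adjusted over the list alone, median 0.43, camera adjusted p = 0.0008, and adjusted p = 0.662 with an estimated correlation). GABARAPL1 rose from 52.4 ± 3.18 to 216 ± 35.1 CPM, MAP1LC3B from 219 ± 14.2 to 434 ± 58.8 CPM and the protease CTSL from 96.9 ± 1.03 to 182 ± 35.0 CPM. For the unfolded-protein response of the endoplasmic reticulum (ER), 4 of 15 genes rose and none fell (2 and 0 adjusted over the list alone). The chaperone HSP90B1 rose from 1458 ± 55.6 to 2315 ± 202 CPM and HERPUD1 from 47.5 ± 2.27 to 77.7 ± 16.9 CPM. Camera called this list (adjusted p = 0.0194; adjusted p = 0.662 with an estimated correlation) with a median of 0.36, but not without siCtrl OSS replicate 1 (0.0653) or replicate 3 (0.0757), nor on the deposited CPM (0.0812).

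Genes of BMP signalling moved strongly under OSS, with 9 of 17 higher and 1 lower (11 and 1 adjusted over the list alone). The list had a median of 1.01 and camera adjusted p = 0.00123 (adjusted p = 0.1001 with an estimated correlation). The intracellular inhibitor SMAD6 rose from 11.6 ± 0.860 to 200.3 ± 41.5 CPM (4.03 ± 0.32) and the BMP target ATOH8 from 2.46 ± 0.465 to 26.0 ± 9.69 CPM (3.11 ± 0.25). The ligand BMP2 rose from 59.0 ± 2.42 to 202 ± 10.1 CPM (1.77 ± 0.16). The ligand BMP4 fell from 137 ± 16.8 to 15.5 ± 0.706 CPM (-3.10 ± 0.19).

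Of 19 mitosis genes 5 fell and none rose under OSS in siCtrl cells (5 and 0 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.0108; adjusted p = 0.662 with an estimated correlation). CDC20 fell from 29.6 ± 4.23 to 12.9 ± 1.55 CPM (-1.17 ± 0.26), AURKB from 8.07 ± 0.784 to 3.88 ± 1.17 CPM and BUB1B from 23.4 ± 2.72 to 9.92 ± 5.66 CPM. Without static siCtrl replicate 1 the camera call was lost (adjusted p = 0.0526). DNA replication genes had 8 of 20 lower and none higher (9 and 0 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 0.00774; adjusted p = 0.662 with an estimated correlation). They included the loading factor CDC6 (-1.40 ± 0.30), the ribonucleotide reductase subunit RRM2 (-1.17 ± 0.26) and the helicase subunit MCM6 (-0.67 ± 0.18). Of 21 targets of MYC and genes of ribosome biogenesis 6 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.0235; adjusted p = 0.662 with an estimated correlation). POLR1B, a subunit of RNA polymerase I, fell from 48.7 ± 3.00 to 14.5 ± 5.21 CPM. CAD, which begins pyrimidine synthesis, fell from 55.5 ± 4.59 to 22.2 ± 8.26 CPM, and the nucleolar protein gene NOP56 from 73.7 ± 4.96 to 37.7 ± 7.37 CPM. Without siCtrl OSS replicate 3 the call of this list was lost (0.0770). In the same libraries 8 of 13 mitochondrially encoded genes fell and none rose (10 lower and 1 higher adjusted over the list alone), with a median of -0.87 (camera adjusted p = 0.00314; adjusted p = 0.662 with an estimated correlation). MT-ND4 fell from 8065 ± 649 to 3922 ± 436 CPM.

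Other vascular and stress lists held large changes in both directions, and camera did not call them. Of 15 genes of angiogenic tip cells 6 fell and 3 rose (7 and 3 adjusted over the list alone, median -0.40, camera adjusted p = 0.154, adjusted p = 0.662 with an estimated correlation). The peptide ligand APLN fell from 166 ± 44.8 to 10.01 ± 6.57 CPM, the Notch ligand DLL4 from 194 ± 19.1 to 20.02 ± 16.7 CPM and the chemokine receptor CXCR4 from 409 ± 46.8 to 46.7 ± 29.4 CPM. In the hypoxia list 4 genes rose and 5 of 15 fell (4 and 5 adjusted over the list alone, median -0.31, camera adjusted p = 0.937, adjusted p = 0.935 with an estimated correlation). Its mean was positive at 0.13 and the direction of camera lower, with KDM3A (2.27 ± 0.12) and NDRG1 (2.41 ± 0.22) higher and the collagen cross-linking enzyme LOX (-1.08 ± 0.16) lower. Of 14 genes of the amino-acid response of ATF4, 6 rose and 3 fell (6 and 4 adjusted over the list alone, median 0.15 and of the other sign on the deposited CPM, camera adjusted p = 0.209, adjusted p = 0.662 with an estimated correlation). ATF4 itself rose from 68.5 ± 6.86 to 204 ± 42.1 CPM. Among 14 immediate early genes 6 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.247, adjusted p = 0.662 with an estimated correlation), including FOSL1 (1.88 ± 0.18) and NR4A1 (3.21 ± 0.47), both higher. Endothelial identity genes went both ways, 5 of 28 higher and 9 lower (5 and 9 adjusted over the list alone, camera adjusted p = 0.716, adjusted p = 0.891 with an estimated correlation). SOX17 rose from 38.2 ± 3.12 to 154 ± 54.1 CPM and KDR, the VEGF receptor, from 788 ± 66.0 to 1466 ± 171 CPM, while SOX7 fell from 82.9 ± 3.31 to 31.0 ± 6.77 CPM. The median of that list was 0.03, its mean -0.18 and the direction of camera lower, and the medians of this list and of the ATF4 list changed sign with the scaling of the libraries.

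Of 19 target genes attributed to FOXO factors, 6 rose, 5 fell and 8 did not pass under OSS (6 and 5 adjusted over the list alone). The median was 0.35, the mean -0.33 and the direction of camera lower (adjusted p = 0.692; adjusted p = 0.891 with an estimated correlation). PDK4, a brake on glucose oxidation, fell from 26.9 ± 0.834 to 1.67 ± 0.578 CPM (-3.69 ± 0.27) and SESN3 from 5.22 ± 0.241 to 0.254 ± 0.148 CPM (-2.94 ± 0.22). The pro-apoptotic BCL2L11 fell from 55.2 ± 4.31 to 11.6 ± 2.79 CPM (-2.22 ± 0.26), whereas BCL6 rose from 11.3 ± 1.238 to 29.02 ± 8.37 CPM (1.28 ± 0.23). These counts come from TMM scaling, under which 48.4% of the called genes were lower. On the deposited CPM the median of all genes shifted by -0.15 (log2) and limma called 1817 genes higher and 3298 lower (64.5%).

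The second comparison asks what lowering FOXO1 does to cells under OSS, which the series describes as its central contrast. The fatty acid binding protein gene FABP4 fell from 105 ± 12.9 to 4.09 ± 1.67 CPM (log2 fold change -4.59 ± 0.23) and CXCR4 from 46.7 ± 29.4 to 2.36 ± 1.74 CPM (-4.15 ± 0.49). ENPP2, which encodes the lysophospholipid-producing enzyme autotaxin, fell from 11.4 ± 7.29 to 0.658 ± 0.290 CPM (-3.22 ± 0.39) and MEDAG from 48.7 ± 13.7 to 7.23 ± 3.97 CPM (-2.82 ± 0.37). The TIE2 ligand ANGPT2, an established FOXO1 target in endothelium, fell from 426 ± 372 to 54.5 ± 31.6 CPM (-2.76 ± 0.46). It was lower in static siFOXO1 cells too, at 390 ± 19.8 CPM against 1139 ± 88.2 CPM in static siCtrl cells. The largest increases were those of the interferon-induced IFI44L, from 22.8 ± 18.0 to 262 ± 235 CPM (3.40 ± 0.56), and of PTGS1, the constitutive cyclooxygenase, from 0.337 ± 0.145 to 6.15 ± 0.314 CPM (3.00 ± 0.32). HIF3A rose from 1.20 ± 0.793 to 10.8 ± 6.53 CPM (2.72 ± 0.46), the transporter ABCC3 from 1.28 ± 0.422 to 10.7 ± 2.21 CPM (2.66 ± 0.24) and IFITM1 from 8.84 ± 4.61 to 55.2 ± 28.3 CPM (2.56 ± 0.47). Their limma adjusted p-values ran from 5.24e-07 for FABP4 to 0.0102 for IFITM1.

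Interferon-stimulated genes were higher after FOXO1 siRNA under OSS as a list. Of 27 measured genes 8 rose and none fell (24 and 0 adjusted over the list alone), with a median of 1.60 (camera adjusted p = 7.37e-18; adjusted p = 0.361 with an estimated correlation). Fitted on the OSS groups only, limma called 0 of the 27 without the replicate block and 24 with it, so the number called depends on the block. BST2 rose from 104 ± 25.0 to 261 ± 56.6 CPM and IFI6 from 35.4 ± 17.7 to 193 ± 95.8 CPM, the latter call being lost without siCtrl OSS replicate 2 (limma adjusted p = 0.0697). Against the static siCtrl mean, the list's median in single libraries was 2.54, 0.76 and 0.54 in siFOXO1 cells under OSS. It was 0.49, -0.86 and -1.04 in siCtrl cells under OSS, so that in both groups the library numbered 1 lay highest. The same held in static cells, with 0.31, 0.11 and -0.40 in siCtrl and 1.25, 0.61 and 0.85 in siFOXO1 libraries. Without siCtrl OSS replicate 1 the list's median was 2.06, and without siFOXO1 OSS replicate 1 it was 1.01.

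NRF2 genes were higher again, with 3 of 14 risen and none fallen (6 and 0 adjusted over the list alone), a median of 0.53 and camera adjusted p = 0.000131 (adjusted p = 0.146 with an estimated correlation). Fitted on the OSS groups only, 1 of the 14 was called without the block and 4 with it. NQO1 rose from 176 ± 10.2 to 403 ± 16.5 CPM (1.19 ± 0.11). The ferritin genes FTH1 (0.99 ± 0.22) and FTL (0.93 ± 0.21) were also called, though FTH1 was lost without siCtrl OSS replicate 2 or siFOXO1 OSS replicate 2 or 3 (adjusted p up to 0.104) and FTL in 8 of the 12 fits without a library (up to 0.130). Mitosis genes had a median of 0.47 with no member called over all genes (6 higher and 0 lower adjusted over the list alone). PLK1 stood at 17.6 ± 1.42 and 26.8 ± 4.47 CPM in siCtrl and siFOXO1 cells (camera adjusted p = 5.02e-06; adjusted p = 0.411 with an estimated correlation). Without both OSS libraries numbered 1 that median was 0.21. The p53 targets had a median of 0.42 with no member called over all genes (3 and 0 adjusted over the list alone; camera adjusted p = 6.04e-05, adjusted p = 0.411 with an estimated correlation). BBC3 stood at 2.31 ± 1.23 and 5.02 ± 1.63 CPM. Nuclear-encoded genes of oxidative phosphorylation had a median of 0.20 (camera adjusted p = 0.000485; adjusted p = 0.497 with an estimated correlation). DNA replication genes had a median of 0.34 (0.00582; adjusted p = 0.620 with an estimated correlation). Neither list had a member called over all genes or adjusted over the list alone. NDUFB3 stood at 39.1 ± 7.15 and 56.6 ± 4.47 CPM, and MCM7 at 21.9 ± 4.47 and 35.1 ± 11.2 CPM. The DNA replication call was lost without siFOXO1 OSS replicate 1 (0.681). The fit of the OSS groups only called no member of these last 4 lists, and with the block 1 p53 target higher.

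Angiogenic tip-cell genes were lower, 4 of 15 fallen and none risen (0 higher and 6 lower adjusted over the list alone), with a median of -0.47 (camera adjusted p = 4.6e-05; adjusted p = 0.0645 with an estimated correlation). On the OSS groups only 1 of the 15 was called lower without the block and 6 with it. Beside CXCR4 and ANGPT2 they included the basement membrane genes NID2, from 17.0 ± 3.14 to 4.98 ± 0.732 CPM (-1.67 ± 0.22), and LAMA4. The latter fell from 878 ± 74.2 to 573 ± 28.5 CPM (-0.61 ± 0.12) and was lost without siCtrl OSS replicate 2 (limma adjusted p = 0.0555). Genes of the ER unfolded-protein response, of which 4 of 15 rose under OSS in siCtrl cells, had 2 of 15 lower and none higher (3 and 0 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.00329; adjusted p = 0.480 with an estimated correlation). SEL1L fell from 470.0 ± 70.5 to 249.6 ± 27.4 CPM (-0.91 ± 0.14) and HYOU1 from 384 ± 58.2 to 223 ± 23.4 CPM (-0.77 ± 0.14). The camera call was lost without siCtrl OSS replicate 3 (0.0539) or siFOXO1 OSS replicate 2 (0.212). Notch and arterial genes had 2 of 19 lower and none higher (1 higher and 5 lower adjusted over the list alone), with a median of -0.35 (camera adjusted p = 0.0337; adjusted p = 0.375 with an estimated correlation). This call was lost without siCtrl OSS replicate 1 (0.112) or siFOXO1 OSS replicate 1 (0.182). They were CXCR4, which is in the tip-cell list too, and the arterial ephrin EFNB2, from 762 ± 49.0 to 458 ± 126 CPM, lost in 3 of the 12 fits without a library (limma adjusted p up to 0.0998). Of 4 markers of lymphatic endothelium 2 fell and none rose (3 and 0 adjusted over the list alone), with a median of -1.14 (camera adjusted p = 0.00397; adjusted p = 0.146 with an estimated correlation). They were the receptor FLT4, from 10.6 ± 1.39 to 3.93 ± 1.09 CPM, and LYVE1, from 11.7 ± 2.59 to 4.50 ± 2.33 CPM, the latter lost in 9 of the 12 fits without a library (limma adjusted p up to 0.133). In the fit of the OSS groups only the numbers lower were 0 for ER genes, 1 for Notch genes and 0 for lymphatic markers, and with the block 2, 5 and 2.

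The FOXO target list was not called in this comparison, with 1 of 19 genes higher and 3 lower (1 and 3 adjusted over the list alone), a median of -0.16 and camera adjusted p = 0.327 (adjusted p = 0.641 with an estimated correlation). TXNIP, an inhibitor of thioredoxin and glucose uptake, rose from 141 ± 61.7 to 352 ± 75.4 CPM (1.37 ± 0.24). The insulin receptor gene INSR fell from 38.8 ± 4.53 to 19.5 ± 8.17 CPM (-1.05 ± 0.23) and PIK3IP1 from 13.6 ± 3.90 to 6.49 ± 0.746 CPM (-0.99 ± 0.22). The former call was lost without siCtrl OSS replicate 2 or 3 or siFOXO1 OSS replicate 3 (limma adjusted p up to 0.0987) and the latter without static siCtrl replicate 2, siCtrl OSS replicate 3 or siFOXO1 OSS replicate 2 (up to 0.0889). Of 19 genes of fatty acid oxidation and uptake 2 fell and none rose (2 and 0 adjusted over the list alone), FABP4 and FABP5, the latter from 122 ± 55.8 to 33.3 ± 6.69 CPM (-1.78 ± 0.25). The list's median was 0.16, its mean -0.21 and the direction of camera higher (adjusted p = 0.867; adjusted p = 0.939 with an estimated correlation). Endothelial identity genes had 2 of 28 higher and 3 lower (5 and 4 adjusted over the list alone, camera adjusted p = 0.892, adjusted p = 0.959 with an estimated correlation). They had a mean of 0.11, a direction of camera higher, and a median of -0.04 that changed sign with the scaling. The junction gene PECAM1 fell from 7419 ± 581 to 4165 ± 999 CPM and TIE1 from 458 ± 59.3 to 271 ± 39.9 CPM, calls lost without siCtrl OSS replicate 2 (0.0697) and replicate 3 (0.0524) respectively. In the laminar-flow list KLF4 alone was called, rising from 12.9 ± 6.43 to 55.3 ± 9.89 CPM (2.19 ± 0.37, limma adjusted p = 0.00619). In the inflammatory list the adhesion molecule ICAM1 rose from 42.1 ± 14.3 to 95.8 ± 11.9 CPM (1.22 ± 0.23, adjusted p = 0.0124, and 0.0570 without siCtrl OSS replicate 2). Camera did not call the laminar-flow list (1 of 15 higher, none lower, 1 and 0 adjusted over the list alone, adjusted p = 0.482; adjusted p = 0.620 with an estimated correlation). It did not call the inflammatory list (0.0686, with 1 of 23 higher, 4 and 1 adjusted over the list alone; adjusted p = 0.667 with an estimated correlation) or the ATF4 list (0.0541, with none of 14 called over all genes or adjusted over the list alone; adjusted p = 0.375 with an estimated correlation). With the replicate block over all 12 libraries camera gave 0.0338 for both of these last lists. The fit of the OSS groups only called 1 fatty acid gene lower and no other member of the lists in this paragraph. With the block it called 1 FOXO target higher and 3 lower, 2 fatty acid genes lower, 5 endothelial identity genes higher and 2 lower, and 2 laminar-flow and 4 inflammatory genes higher.

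In all, limma called 173 genes higher and 303 lower after FOXO1 siRNA under OSS. With replicate number as a block over all 12 libraries it called 274 and 420. That block joins static and OSS libraries, whose equally numbered members correlated at most at 0.139 within an siRNA. Fitted on the OSS libraries alone, whose spread is wider than that of the static libraries, limma called 8 and 17 without the block. All 25 of these were among the 476, and with the block it called 278 and 374. Without siCtrl OSS replicate 2 it called 66 higher and 183 lower, and without siCtrl OSS replicate 1, 357 higher and 485 lower.

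**Figure D2:**
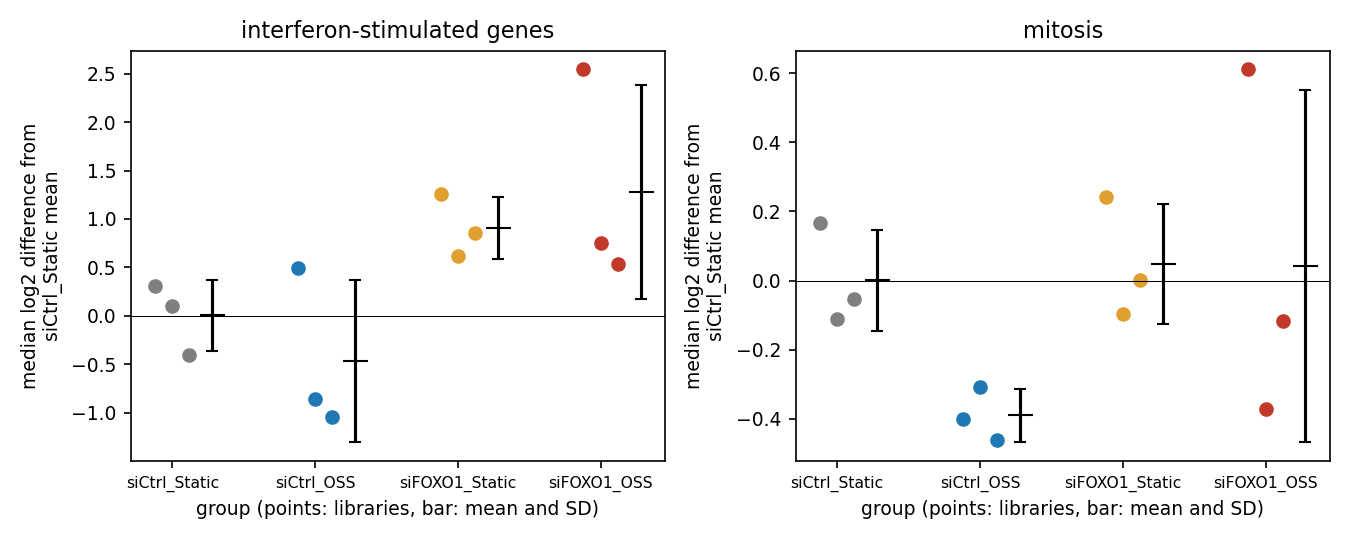
Median log2 difference of 27 interferon-stimulated genes and of 19 mitosis genes from the static siCtrl mean (vertical axes) in the 4 groups (horizontal axes), with a point for each library and a bar for the mean and SD of 3 libraries. The interferon list reads 2.54, 0.76 and 0.54 in the siFOXO1 OSS libraries against 0.49, -0.86 and -1.04 in the siCtrl OSS libraries.

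The third comparison is the same knockdown in static cells. CXCR4 fell from 409 ± 46.8 to 36.5 ± 7.15 CPM (log2 fold change -3.48 ± 0.49) and ENPP2 from 15.5 ± 6.78 to 1.003 ± 0.171 CPM (-3.34 ± 0.39). MS4A6A fell from 5.69 ± 0.303 to 0.491 ± 0.297 CPM (-2.69 ± 0.40) and FABP4 from 189.9 ± 21.9 to 30.1 ± 5.09 CPM (-2.65 ± 0.23). FABP5P7, a pseudogene whose reads are hard to tell from those of FABP5, fell with it (-2.73 ± 0.52), a call lost without any of the 3 static siCtrl libraries (limma adjusted p up to 0.141). FABP5 fell from 214 ± 26.3 to 54.6 ± 7.12 CPM (-1.96 ± 0.25). The largest increases were those of MYRIP, a motor adaptor of secretory granules, from 5.67 ± 0.646 to 31.6 ± 2.82 CPM (2.38 ± 0.28), and of ABCC3, from 1.42 ± 0.202 to 9.19 ± 1.78 CPM (2.33 ± 0.24). The integrin ITGB4 rose from 0.739 ± 0.613 to 4.89 ± 1.19 CPM (2.21 ± 0.32), the prostaglandin transporter SLCO2A1 from 6.26 ± 0.496 to 31.6 ± 9.24 CPM (2.21 ± 0.22) and PTGS1 from 0.165 ± 0.112 to 2.71 ± 1.79 CPM (2.15 ± 0.32). Their limma adjusted p-values ran from 0.000489 for FABP4 to 0.0241 for FABP5P7.

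Angiogenic tip-cell genes were lower as a list in static cells, 3 of 15 lower and none higher (7 and 0 adjusted over the list alone), with a median of -0.51. This was the only list of the 5 contrasts that camera called with both the preset correlation (adjusted p = 1.12e-08) and an estimated one (adjusted p = 0.00997 with an estimated correlation). In the fit of the static groups only 6 of the 15 were lower (8 with the block). There camera called the list with the preset correlation (adjusted p = 2.67e-07) but not with an estimated one (adjusted p = 0.323). Beside CXCR4 the growth factor PGF fell from 132 ± 6.45 to 55.0 ± 6.89 CPM (-1.26 ± 0.15). NRF2 genes had 1 of 14 higher and none lower (5 and 0 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 9.59e-07; adjusted p = 0.0681 with an estimated correlation). Fitted on the static groups only, whose spread was narrower, limma called 9 of the 14 higher with or without the block. NQO1 rose from 84.2 ± 5.92 to 169 ± 11.8 CPM (1.004 ± 0.11). No interferon-stimulated gene of 27 was called over all genes (3 and 0 adjusted over the list alone), but 16 were called higher in the fit of the static groups only (20 with the block), so the number called depends on the fit and does not set static cells apart from cells under OSS. The list had a median of 0.91 (camera adjusted p = 5.53e-10; adjusted p = 0.426 with an estimated correlation). BST2 stood at 69.6 ± 19.5 and 136 ± 23.4 CPM in siCtrl and siFOXO1 cells. The inflammatory list had a median of 0.44 with no member of 23 called (1 and 0 adjusted over the list alone; camera adjusted p = 0.0168, adjusted p = 0.576 with an estimated correlation). In the fit of the static groups only 7 of the 23 were called higher (9 with the block). ICAM1 stood at 18.9 ± 1.50 and 36.8 ± 10.7 CPM. That call was lost without static siFOXO1 replicate 1 (0.220).

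The ER unfolded-protein list had a median of -0.17 in static cells with no member of 15 called (0 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.000216, adjusted p = 0.426 with an estimated correlation). In the fit of the static groups only 5 of the 15 were lower, with or without the block. HYOU1 stood at 388 ± 18.6 and 251 ± 22.8 CPM. Notch and arterial genes had 1 of 19 lower, CXCR4 (0 higher and 2 lower adjusted over the list alone), with a median of -0.30 (camera adjusted p = 0.0168; adjusted p = 0.355 with an estimated correlation). Of 7 fibroblast markers THY1 fell from 4.08 ± 1.49 to 0.443 ± 0.0343 CPM (-2.23 ± 0.28) and no other was called (0 higher and 1 lower adjusted over the list alone). The list median was -0.43 (camera adjusted p = 0.0185, and 0.208 without static siCtrl replicate 1; adjusted p = 0.355 with an estimated correlation). Mitochondrially encoded genes had a median of -0.35 with none of 13 called over all genes or over the list alone (camera adjusted p = 1.89e-05, and 0.0724 without static siFOXO1 replicate 1; adjusted p = 0.426 with an estimated correlation). MT-CO3 stood at 4219 ± 454 and 3103 ± 631 CPM. Glycolysis genes had 1 of 20 lower and none higher (1 and 0 adjusted over the list alone), a median of -0.04 and camera adjusted p = 0.0447 (adjusted p = 0.426 with an estimated correlation). It was lost without static siCtrl replicate 3 (0.133), static siFOXO1 replicate 2 (0.0519) or replicate 3 (0.121) and on the deposited CPM (0.0579). The gene was PGAM1, from 123 ± 2.48 to 72.3 ± 10.9 CPM, itself lost in 7 of the 12 fits without a library (limma adjusted p up to 0.205). The p53 targets and the pair of leukocyte markers, CD14 and LAPTM5, each reached camera adjusted p = 0.0477 with no member called (adjusted p = 0.685 and adjusted p = 0.355 with an estimated correlation; over the list alone 0 and 0 for p53, and 0 higher and 1 lower for leukocytes). The p53 call was lost without static siCtrl replicate 1 or 3, siCtrl OSS replicate 1 or 2, static siFOXO1 replicate 1 or 2, or siFOXO1 OSS replicate 1 (0.0508 to 0.108). The leukocyte call was lost without static siCtrl replicate 3, siCtrl OSS replicate 1 or 2, static siFOXO1 replicate 1 or 3, or siFOXO1 OSS replicate 1 (0.0508 to 0.133). The static groups fitted alone had 5 p53 targets higher and 2 lower (6 and 2 with the block) and 1 leukocyte marker lower (1 with the block). They had 1 Notch gene higher and 5 lower (1 and 6), 4 glycolysis genes lower (4), 1 fibroblast marker lower (1) and no mitochondrially encoded gene called (4 lower). In the fit of the static groups only, camera did not call the fibroblast (adjusted p = 0.111) or leukocyte (0.182) lists.

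FOXO targets in static cells had 1 of 19 higher and 1 lower (1 and 3 adjusted over the list alone), a median of -0.03 and camera adjusted p = 0.241 (adjusted p = 0.576 with an estimated correlation). SESN3 fell from 5.22 ± 0.241 to 1.46 ± 0.0664 CPM (-1.55 ± 0.22). TXNIP rose from 104 ± 3.05 to 279 ± 27.7 CPM (1.42 ± 0.24), a call lost in 5 of the 12 fits without a library (limma adjusted p up to 0.0703). In the laminar-flow list, which camera did not call (adjusted p = 0.967; adjusted p = 0.980 with an estimated correlation), 1 of 15 genes was higher and 2 lower (2 and 2 adjusted over the list alone). The anticoagulant receptor THBD fell from 121 ± 10.9 to 39.5 ± 2.26 CPM (-1.60 ± 0.25, lost without static siCtrl replicate 3, 0.0559). The list's median was 0.12, its mean 0.04 and the direction of camera lower. Fatty acid genes, with FABP4 and FABP5, had 2 of 19 lower and none higher (2 and 0 adjusted over the list alone), a median of 0.06 and a mean of -0.18, with camera lower (adjusted p = 0.699; adjusted p = 0.715 with an estimated correlation). In the fit of the static groups only, 2 FOXO targets were higher and 5 lower (3 and 6 with the block), 2 laminar-flow genes higher and 2 lower (4 and 2), and 2 fatty acid genes higher and 3 lower (3 and 3). In all, limma called 60 genes higher and 83 lower. Fitted on the static libraries alone, whose spread is narrower than the shared one, it called 797 and 849, with all 143 among them. Without static siCtrl replicate 3 it called 12 and 34, and without siFOXO1 OSS replicate 1, which enters only through the shared spread, 118 and 135.

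**Figure D3:**
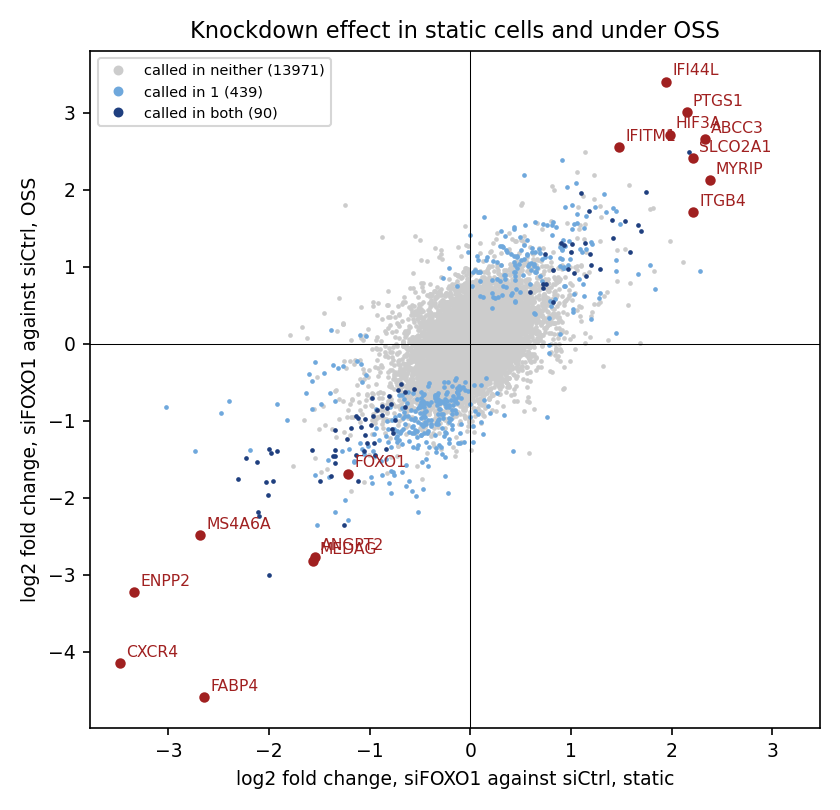
Log2 fold change after FOXO1 siRNA in static cells (horizontal axis) against that under OSS (vertical axis), with a point for each of 14503 genes, coloured by whether limma called it in both contrasts. The genes called in both lie along the diagonal, 33 of them higher and 57 lower, and the genes named in the text are marked in red.

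The knockdown effects in static and OSS cells correlated across the 14503 genes at r = 0.566 (Spearman rho = 0.450). Genes are not independent replicates, and the contrasts share no library. Of the genes called higher in static cells 33 were also higher under OSS, where independent calls would give 0.716, and 57 were lower in both, against 1.73. Both contrasts use the same estimated spread of each gene, so unrelated effects would give more shared calls than independence does. CXCR4, ENPP2, FABP4 and FABP5 were among the genes lower in both, and PTGS1, ABCC3, NQO1 and TXNIP among those higher in both.

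The fourth comparison repeats the OSS response in siFOXO1 cells. CYP1B1 rose from 0.312 ± 0.153 to 109 ± 15.9 CPM (log2 fold change 7.08 ± 0.33) and PTGS2 from 39.5 ± 12.7 to 2762 ± 840.0 CPM (6.11 ± 0.31). F3 rose from 0.537 ± 0.240 to 67.3 ± 40.6 CPM (5.84 ± 0.44), HMOX1 from 22.0 ± 3.62 to 759.6 ± 241 CPM (5.04 ± 0.30) and KLF4 from 1.42 ± 0.458 to 55.3 ± 9.89 CPM (4.87 ± 0.37). The largest decreases were those of DEPP1 (-5.18 ± 0.68), the inositol transporter SLC5A3, from 176 ± 23.7 to 5.20 ± 0.806 CPM (-4.95 ± 0.20), KIT (-4.86 ± 0.26), DLL4, from 138 ± 9.38 to 5.17 ± 3.04 CPM (-4.80 ± 0.49), and FLRT2 (-4.21 ± 0.33). Their limma adjusted p-values ran from 1.84e-08 for SLC5A3 to 0.000129 for DEPP1. In all, limma called 2710 genes higher and 2680 lower, and 2097 and 3326 on the deposited CPM, where the median of all genes shifted by -0.11.

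Camera called 5 lists in this comparison. The inflammatory list had 12 of 23 genes higher and 3 lower (12 and 3 adjusted over the list alone), with a median of 1.10 (camera adjusted p = 0.00700, and 0.0611 without siFOXO1 OSS replicate 1; adjusted p = 0.689 with an estimated correlation). SELE rose from 3.81 ± 0.522 to 139 ± 75.0 CPM (4.86 ± 0.46) and the chemokine CX3CL1 fell from 7.48 ± 0.678 to 1.46 ± 0.292 CPM (-2.03 ± 0.28). BMP genes had 10 of 17 higher and 1 lower (12 and 1 adjusted over the list alone), with a median of 1.13 (camera adjusted p = 0.00051; adjusted p = 0.0686 with an estimated correlation). They included ATOH8 (4.44 ± 0.25), SMAD6 (3.85 ± 0.32) and SMAD7 (3.29 ± 0.32). NRF2 genes had 9 of 14 higher and none lower (9 and 0 adjusted over the list alone), with a median of 0.81 (camera adjusted p = 9.13e-05; adjusted p = 0.138 with an estimated correlation). Autophagy genes had 8 of 18 higher and none lower (8 and 0 adjusted over the list alone, median 0.42, camera adjusted p = 0.00533, adjusted p = 0.689 with an estimated correlation). Nuclear-encoded genes of oxidative phosphorylation had 16 of 32 higher and none lower (17 and 0 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.00051; adjusted p = 0.689 with an estimated correlation). UQCRFS1 rose from 44.4 ± 5.15 to 98.5 ± 17.2 CPM (1.13 ± 0.18) and SDHB from 43.8 ± 2.25 to 72.8 ± 5.68 CPM (0.73 ± 0.15). Interferon-stimulated genes were not called as a list, with 6 of 27 higher and none lower (6 and 0 adjusted over the list alone, median 0.25, camera adjusted p = 0.237, adjusted p = 0.893 with an estimated correlation). IFI27 rose from 178 ± 47.1 to 513 ± 183 CPM (1.50 ± 0.29).

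**Figure D4:**
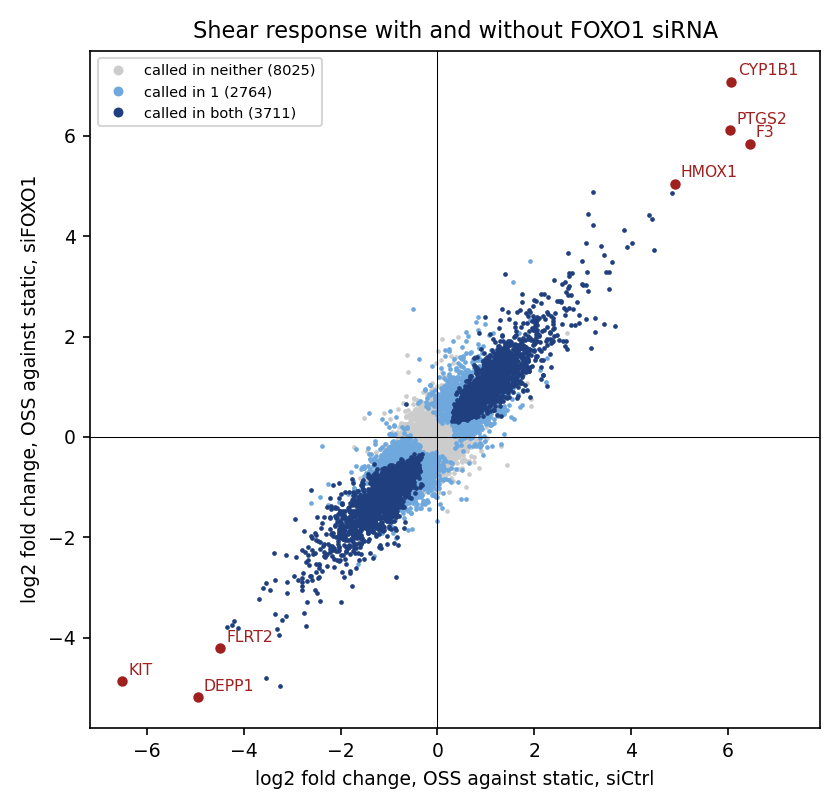
Log2 fold change under OSS in siCtrl cells (horizontal axis) against that in siFOXO1 cells (vertical axis). Each point is 1 of the 14503 tested genes, without those not reported here, coloured by whether limma called it in both contrasts. Of the genes called in both, 1944 were higher in both and 1766 lower in both, with a correlation of 0.892 over all genes. Marked in red are the genes named for the largest changes in both contrasts.

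The OSS responses of siCtrl and siFOXO1 cells correlated at r = 0.892 across the 14503 genes (Spearman rho = 0.866). The slope was 0.931 for siFOXO1 on siCtrl cells and 0.855 for siCtrl on siFOXO1 cells. As the reverse slope is lower still, the value of 0.931 does not show a weaker response in siFOXO1 cells. Of the genes higher under OSS in siCtrl cells 1944 were also higher in siFOXO1 cells (463 with independent calls), and 1766 were lower in both (429). These contrasts, too, use the same estimated spread of each gene, so independence understates the count for unrelated responses. The interaction, which tests the difference between the responses gene by gene, gave 0 genes with limma at an adjusted p under 0.05. The smallest adjusted p was 0.120, and 535 genes had an unadjusted p under 0.05, where 725 would do so by chance. With a pseudocount of 2 CPM limma called 3 genes with a more positive response in siFOXO1 cells (SESN3, KIT and ACSM3) and 2 with a more negative one (NPTN and ELK3), and without the OSS libraries numbered 1 it called 2 and 9. These genes were named after their values were seen. Under OSS, KIT and SESN3 stood at 0.624 and 0.254 CPM in siCtrl cells. In siFOXO1 cells they stood at 0.152 and 0.141 CPM, so all these values lie below the added 2 CPM. With that pseudocount the size of their falls largely follows their static levels. These levels were 98.9 and 5.22 CPM in siCtrl and 18.4 and 1.46 CPM in siFOXO1 cells. The interaction could detect less than the other contrasts, as its median SE of 0.330 against 0.233 shows.

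Camera called 7 lists in the interaction, all with a more positive OSS response in siFOXO1 cells and none with a member called over all genes. Camera without the trend also called the lymphatic markers, with a more negative response (median -0.55, adjusted p = 0.0430, against 0.0550 with the trend). Mitosis genes had a median difference of 0.41 (adjusted p = 1.85e-07; adjusted p = 0.797 with an estimated correlation). It was 0.20 without the OSS libraries numbered 1 (adjusted p = 0.0435). The list's medians in the siFOXO1 OSS libraries were 0.61, -0.37 and -0.12 against the static siCtrl mean, replicate 1 standing highest. UBE2C stood at 11.3 ± 2.87 and 8.08 ± 2.14 CPM in static and OSS siCtrl cells and 8.90 ± 2.06 and 12.8 ± 0.626 CPM in siFOXO1 cells. Interferon-stimulated genes had a median of 0.80 (adjusted p = 2.22e-06; adjusted p = 0.797 with an estimated correlation). ISG15 stood at 9.50 ± 2.31 and 8.85 ± 2.82 CPM in siCtrl and 10.3 ± 1.75 and 30.8 ± 15.1 CPM in siFOXO1 cells. Nuclear-encoded oxidative phosphorylation genes had a median of 0.24 (camera adjusted p = 7.25e-05), DNA replication genes 0.41 (0.000383), mitochondrially encoded genes 0.36 (0.000401), p53 targets 0.40 (0.0138) and the pair of leukocyte markers 0.85 (0.00656). For these the adjusted p = 0.797 with an estimated correlation held for the first 3, and it was 0.887 for p53 and 0.369 for leukocyte markers. Adjusted over the list alone, CD14 of the leukocyte pair was higher, and no member of the other 6 lists. The interferon call was lost without siFOXO1 OSS replicate 1 (camera adjusted p = 0.352), as were those of DNA replication (0.551) and p53 (0.352). The p53 call was also lost without static siCtrl replicate 2 (0.0516), siCtrl OSS replicate 2 (0.749) or siFOXO1 OSS replicate 3 (0.0933), and the mitochondrially encoded call without static siFOXO1 replicate 1 (0.279).

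**Figure D5:**
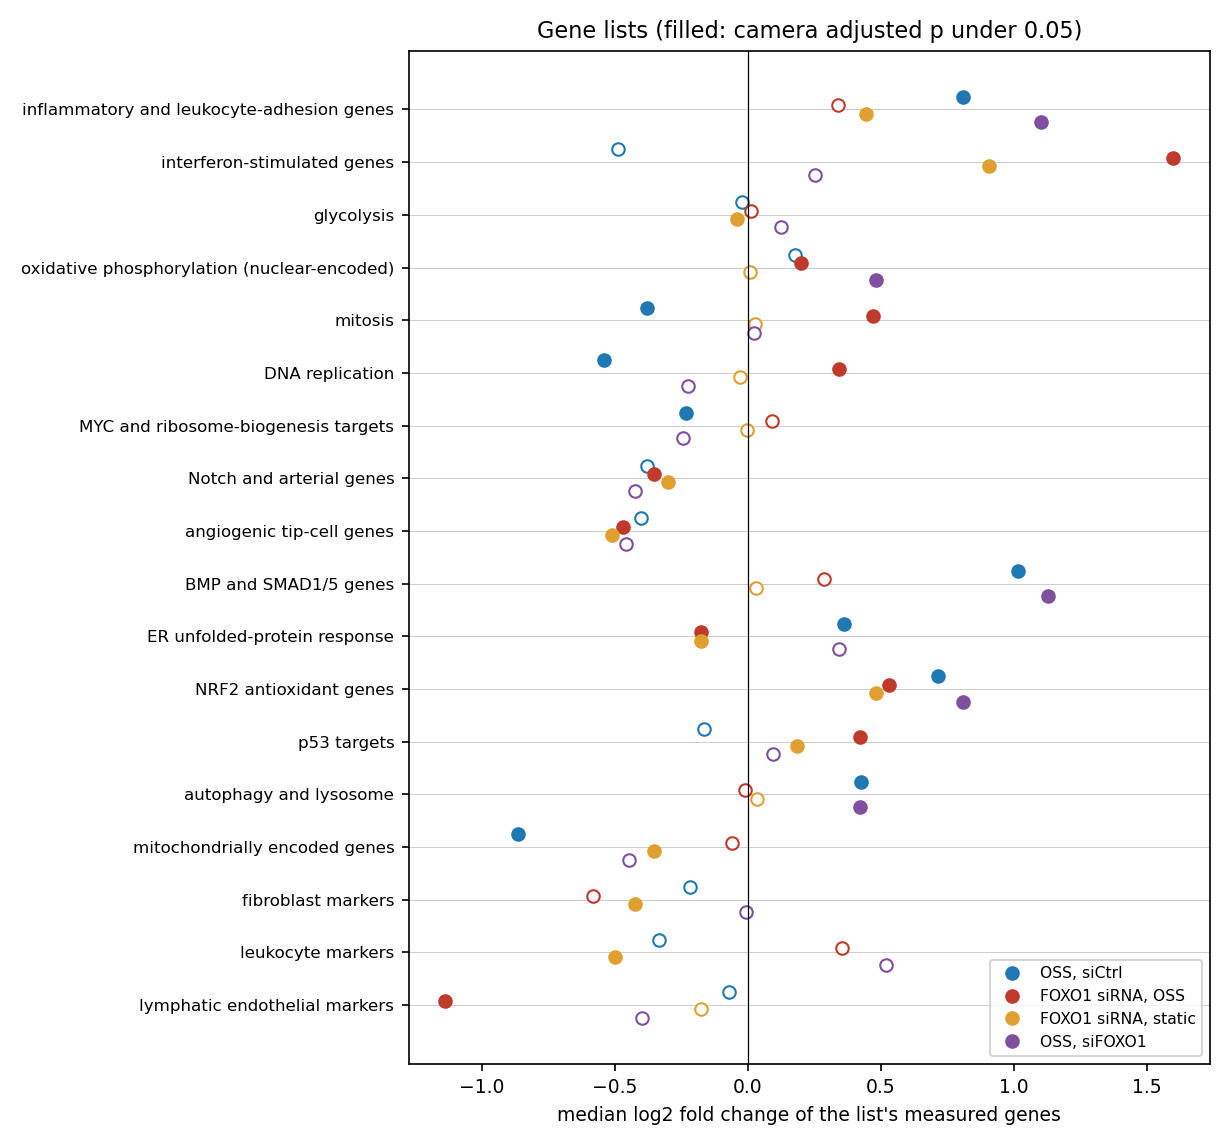
Median log2 fold change (horizontal axis) of the gene lists that camera called in at least 1 pairwise contrast (vertical axis), with a circle for each list and contrast, coloured by contrast and filled where camera gave an adjusted p under 0.05. The interferon list reads 1.60 after FOXO1 siRNA under OSS and 0.91 in static cells, and the NRF2 list is positive in all 4 pairwise contrasts, at 0.72, 0.53, 0.48 and 0.81.

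The last question was whether genes moved by OSS in control cells moved the other way when FOXO1 was lowered under OSS. Across the 14503 genes, the OSS response in siCtrl cells and the knockdown effect under OSS correlated at r = -0.0430. Both contrasts use the siCtrl OSS libraries, which are too few to be split. In simulated data with unchanged, independent groups of equal spread the correlation was -0.498 and the covariance -0.0342, against an observed covariance of -0.0141. The simulation leaves out the correlated deviations of equally numbered OSS libraries (0.572, 0.329 and 0.299). It also leaves out their wider spread (median SD 0.299 in siCtrl OSS and 0.114 in static siCtrl libraries). The distance from the simulated values is therefore not read as a response. Without siFOXO1 OSS replicate 1 the correlation was 0.162 and the covariance 0.0551, whereas the correlation was -0.226, -0.0929 and -0.0130 without siCtrl OSS replicates 1, 2 and 3. It was -0.123 and -0.147 without siFOXO1 OSS replicates 2 and 3. Among genes changed by OSS, 53.4% had a knockdown effect of the opposite sign, a share for which no simulated value over called genes was made. Of genes higher under OSS 70 were lower after FOXO1 siRNA, and of genes lower under OSS 36 were higher. Genes that went the same way numbered 28 higher in both and 59 lower in both, with no count for unchanged groups to set beside these numbers, CXCR4 being among the latter. SEL1L rose under OSS, with 361 ± 21.3 CPM in static and 470.0 ± 70.5 CPM in OSS siCtrl cells (limma adjusted p = 0.0499, lost in 9 of the 12 fits without a library), and fell after FOXO1 siRNA.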

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

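Of the tests in this part, the 3 on the interferon list, that of a batch shared by all libraries numbered 1 and the fits without both OSS libraries numbered 1 were chosen only after the result was seen. Camera on the interaction found that the OSS response of 7 lists differed between siFOXO1 and siCtrl cells, in each case by being more positive in siFOXO1 cells. The adjusted p was 2.22e-06 for interferon-stimulated genes (median difference 0.80), 1.85e-07 for mitosis (0.41) and 0.000383 for DNA replication (0.41). The mitosis difference was 0.20 without the OSS libraries numbered 1 (adjusted p = 0.0435). The adjusted p was 7.25e-05 for nuclear-encoded oxidative phosphorylation (0.24), 0.000401 for mitochondrially encoded genes (0.36), 0.0138 for p53 targets (0.40) and 0.00656 for the leukocyte markers CD14 and LAPTM5 (0.85). With an estimated correlation none was called (adjusted p from 0.369 to 0.887). Without siFOXO1 OSS replicate 1 the adjusted p was 0.352 for the interferon and p53 lists and 0.551 for DNA replication, and without static siFOXO1 replicate 1 it was 0.279 for the mitochondrially encoded genes. The p53 value was also 0.0516 without static siCtrl replicate 2, 0.749 without siCtrl OSS replicate 2 and 0.0933 without siFOXO1 OSS replicate 3.

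Interferon-stimulated genes had a median of 1.60 after FOXO1 siRNA under OSS with 8 of 27 called higher, though with an estimated correlation the list's adjusted p was 0.361, and the fit of the OSS groups only called 0 without the replicate block and 24 with it. The tables argue against a single library as the whole source, since the median stayed positive when each OSS library was left out in turn (lowest 1.01 without siFOXO1 OSS replicate 1, 2.06 without siCtrl OSS replicate 1). They also argue against the scaling, since the median was 1.63 on the deposited CPM. A response to the siRNA duplex rather than to the loss of FOXO1 could not be told apart from an effect of FOXO1, as both predict a list that is higher in static cells too, where its median was 0.91, and there is no other FOXO1 siRNA among the libraries. An effect of lowered FOXO1 on interferon genes, the biological candidate, may therefore hold but stays open beside the duplex.

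The OSS libraries numbered 1 of both arms stood apart from the other OSS libraries, and across genes their deviations from their group means correlated at 0.572. Depth is argued against as the source, since the correlation was 0.684 over the 3840 genes of at least 50 CPM. For a batch of all libraries numbered 1, the highest correlation with a static library numbered 1 was 0.111. This low value cannot exclude such a batch, since the static libraries deviate little from their group means (median SD 0.114 and 0.138). The interferon list was also highest in the library numbered 1 of all 4 groups, so such a batch stays open. A weaker shear response in the OSS libraries numbered 1 stays open as well. Their deviation had a slope of -0.101 on the other arm's OSS response in siCtrl cells and -0.418 in siFOXO1 cells. A shear run or culture shared by this pair could give the same pattern, and the labels name none, so no biological explanation was tested. Without the pair, limma called 474 genes higher and 680 lower after FOXO1 siRNA under OSS (173 and 303 with all libraries) and the interferon median was 1.50.

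Regrouping the 6 libraries of a contrast gives 10 splits, too few for a share under 0.05. For OSS in siCtrl cells the real split gave 4796 genes and the highest other 0, so that 1 of the 10 reached the real value. For FOXO1 siRNA in static cells the figures were 143 and 0 (1 of 10), and for OSS in siFOXO1 cells 5390 and 1 (1 of 10). For FOXO1 siRNA under OSS the real split gave 476 and the highest other 2104, with 3 of the 10 as large. The larger ones, with 1096 and 2104 genes, kept the OSS libraries numbered 1 together on the same side, which points to a structure of the samples. The other splits that keep this pair together gave 0, however, so the pair alone does not account for these numbers. The split with 1096 genes set the OSS libraries lowest on the first principal component (24.8 to 37.1) against the others (54.6 to 61.5). That with 2104 genes did so along the second component (-54.3 to -16.9 against 8.17 to 40.3). The second component also parted the siRNAs in static cells. What else parts the OSS libraries along these components was not tested. The other splits that part all 3 replicate pairs also gave 0. With the replicate block the real split gave 274 genes higher and 420 lower. For the interaction the real count was 0, which every split reaches (100 of 100 drawn), so this comparison says nothing about chance. The highest drawn split gave 1000 genes, which again points to a structure of the samples.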

How the results depend on the processing

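The deposited CPM, both other pseudocounts, the fits without both OSS libraries numbered 1, the fit of the compared groups with a block, the corrections for GC and length and camera without the trend were chosen after the data were seen. The planned count-based DESeq2 alternative was not run. The table was analysed as CPM, although whole reads can be worked back from it, so how a count model would change the results is not known. Across all settings 445 of the summary values stayed on the same side with the same sign, 65 moved and 2 reversed, 836 list results stayed and 130 lost their call, and 3690 results for named genes stayed and 165 lost their call. No scaling changed the number of genes called by over 1.5 times in either direction, and none changed the relation between contrasts in sign. Depth limited what could be seen in weak genes, since 3 reads were worth up to 0.254 CPM. In data simulated with the same spread in all groups, 38% of 2-fold interaction effects were recovered.

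With the replicate block over all 12 libraries, FOXO1 siRNA under OSS raised 274 genes and lowered 420. With a pseudocount of 2 CPM the interaction gave 3 genes higher and 2 lower. Of these, KIT and SESN3 lay below 2 CPM under OSS in both arms, so their falls largely follow their static levels. For the others the cause was not tested. Without the OSS libraries numbered 1 there were 474 higher and 680 lower for FOXO1 siRNA under OSS, 227 and 262 in static cells, and 2 and 9 in the interaction. Fitted on the compared groups only, FOXO1 siRNA gave 8 and 17 under OSS and 797 and 849 in static cells, where each fit uses its own spread (median SD 0.299 and 0.330 against 0.114 and 0.138), and with the block as well 278 higher and 374 lower under OSS.

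Of the lists called by camera, 9 for OSS in siCtrl cells, 10 and 11 for FOXO1 siRNA under OSS and in static cells, 5 for OSS in siFOXO1 cells and 7 in the interaction, an estimated correlation left 0, 0, 1, 0 and 0. The list left, tip-cell genes in static cells, lost that call too in the fit of the static groups only (camera adjusted p = 0.323). Directional fry, which does not compare a list with other genes, called 19, 4, 4, 20 and 1, and mixed fry 26, 17, 11, 25 and 0. Without the OSS libraries numbered 1, camera lost the inflammatory (adjusted p = 0.0863) and ER (0.0723) lists for OSS in siCtrl cells, DNA replication (0.378) and Notch (0.246) for FOXO1 siRNA under OSS, leukocyte markers in static cells (0.0890), and DNA replication (0.279) and leukocyte markers (0.0868) in the interaction. It gained interferon genes (0.00294, lower) for OSS in siCtrl cells, DNA replication (0.0424) for OSS in siFOXO1 cells, and the inflammatory (0.000272), ATF4 (0.0461) and FOXO family (0.0343) lists for FOXO1 siRNA under OSS. In static cells it gained the cholesterol and YAP and TAZ lists (both 0.0434). The block lost the leukocyte list in static cells (0.0629) and gained the YAP and TAZ list there (0.0456) and the inflammatory and ATF4 lists for FOXO1 siRNA under OSS (both 0.0338). Camera without the trend lost the glycolysis and p53 lists in static cells (both 0.0653) and gained the lymphatic markers in the interaction (0.0430, lower). Fitted on the static groups only, camera lost the fibroblast (0.111) and leukocyte (0.182) lists and gained the cholesterol (0.0243) and YAP and TAZ (0.0233) lists. On the OSS groups only it gained the fibroblast (0.0272) and inflammatory (0.0465) lists for FOXO1 siRNA.

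Leaving out each library, with fewer samples in each fit, gave 1543 (without siCtrl OSS replicate 3) to 2891 genes lower (without siFOXO1 OSS replicate 1) for OSS in siCtrl cells. For FOXO1 siRNA under OSS it gave 66 to 357 higher and 183 to 485 lower, from siCtrl OSS replicates 2 and 1. In static cells it gave 12 to 118 higher and 34 to 135 lower, from static siCtrl replicate 3 and siFOXO1 OSS replicate 1. The interaction had 0 to 2 genes higher and 0 to 2 lower, and 4 to 9 lists. Leaving out siCtrl OSS replicate 1 and siFOXO1 OSS replicate 1 gave the ends of 4 ranges: the correlation of OSS response and knockdown effect, -0.226 to 0.162, their covariance, -0.0949 to 0.0551, the slope of the OSS responses, 0.823 to 1.05, and the share of opposite genes, 63.5% to 39.4%. The sign of the first pair reversed without siFOXO1 OSS replicate 1; the cause was not tested. Named genes lost their call in at least 1 of these fits for 7 of 91 (OSS in siCtrl cells), 13 of 34 and 7 of 22 (FOXO1 siRNA under OSS and in static cells) and 1 of 37 (OSS in siFOXO1 cells). In the fits of the compared groups only, 27 of the 34 named genes under OSS lost their call without the block and 0 with it. None of the 22 in static cells or of the 37 did so, and 2 of the 91 without the block and 1 with it.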

Other observations

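Of the tests in this part, those on the deposited CPM and those corrected for GC content and length were chosen only after the result was seen. Notch and arterial genes moved both ways under OSS in siCtrl cells, 6 of 19 higher, 6 lower and 7 not passed (6 and 7 adjusted over the list alone). Camera did not call the list (median -0.38, adjusted p = 0.422, adjusted p = 0.737 with an estimated correlation). The ligand JAG1 rose from 178 ± 14.5 to 826 ± 187 CPM and the effector HEY2 from 92.2 ± 5.76 to 256 ± 36.2 CPM. The feedback inhibitor NRARP fell from 85.8 ± 4.47 to 15.0 ± 5.15 CPM. In the list of haemostasis and fibrinolysis 4 of 15 genes rose and 3 fell (4 and 3 adjusted over the list alone, median 0.18, camera adjusted p = 0.245, adjusted p = 0.737 with an estimated correlation). VWF, the von Willebrand factor gene, fell from 1638 ± 82.5 to 910.2 ± 84.9 CPM. Mesenchymal and TGF-beta genes had 9 of 19 higher and 2 lower (9 and 2 adjusted over the list alone). They had a median of 0.11 that changed sign with the scaling (camera adjusted p = 0.244, adjusted p = 0.662 with an estimated correlation). CCN2 rose from 2163 ± 208 to 6428 ± 352 CPM and SNAI1 from 3.22 ± 0.722 to 14.5 ± 1.41 CPM. TGFB2 fell from 43.8 ± 8.60 to 9.87 ± 3.14 CPM. The YAP and TAZ targets, which share CCN2 with that list, had 5 of 21 higher and 6 lower (5 and 6 adjusted over the list alone). They had a median of 0.09 that changed sign with the scaling (camera adjusted p = 0.692, adjusted p = 0.891 with an estimated correlation). LATS2 rose from 83.9 ± 5.17 to 235 ± 39.3 CPM.

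Metabolic lists were split as well under OSS in siCtrl cells. Of 19 genes of fatty acid oxidation and uptake 5 fell and 2 rose (5 and 2 adjusted over the list alone, median -0.23, camera adjusted p = 0.375, adjusted p = 0.662 with an estimated correlation). PPARA fell from 36.5 ± 4.38 to 16.5 ± 6.86 CPM, and HADH from 16.2 ± 0.802 to 8.60 ± 1.60 CPM. ACAA2 rose from 56.1 ± 3.53 to 84.8 ± 12.01 CPM. Of 23 genes of cholesterol synthesis 5 rose and 2 fell (5 and 2 adjusted over the list alone, median -0.00, mean 0.08, camera direction higher, camera adjusted p = 0.692, adjusted p = 0.891 with an estimated correlation). The sterol carrier gene STARD4 rose from 54.7 ± 2.32 to 238 ± 95.0 CPM and HMGCS1 from 42.9 ± 1.36 to 84.1 ± 27.1 CPM. Glycolysis genes had 2 of 20 higher and 2 lower (2 and 2 adjusted over the list alone, median -0.02, camera adjusted p = 0.796, adjusted p = 0.899 with an estimated correlation). PDK1 rose from 13.8 ± 0.129 to 38.2 ± 11.6 CPM and PFKM fell from 57.7 ± 2.43 to 37.5 ± 6.16 CPM. Of the markers of other cell types, 4 of 10 for smooth muscle, 7 of 11 for fibroblasts, 2 of 11 for leukocytes and 4 of 6 for lymphatic endothelium were measured. Under OSS in siCtrl cells none of 4 measured smooth muscle markers passed (camera adjusted p = 0.244), and of 7 fibroblast markers 1 rose and 1 fell (0.757). Of 2 leukocyte markers 1 fell (0.692), and of 4 lymphatic markers 1 fell (0.692). After FOXO1 siRNA under OSS the fibroblast list had 1 of 7 genes lower, THY1 (-1.49 ± 0.28, limma adjusted p = 0.0125), and camera adjusted p = 0.0789. The smooth muscle list had 1 of 4 higher (camera adjusted p = 0.892).

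On the deposited CPM more of the genes changed by OSS in siCtrl cells were lower (3298, 64.5%) than higher (1817), whereas with TMM scaling 48.4% were lower. The tables argue against a few abundant genes that take up more reads under OSS, since rescaling to the reads outside the 100 most abundant genes left 63.8% lower. They also argue against GC content and transcript length as the source of the calls, since limma called 5110 genes after a correction for GC content and 4903 after one for length, against 4796 without, though these tests bear on the number called and not on its split. What stays open is whether the true centre of the changes lies at the TMM value or at the deposited one, a shift of -0.15 (log2) in the median gene, which relative counts without a spiked-in standard could not decide.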
